A study of Apis mellifera with 11 samples.

How the data were processed

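Messenger RNA was measured by stranded RNA sequencing in brains of caged worker honey bees (Apis mellifera) aged 15 days. The bees had been infected 13 days earlier with the microsporidian gut parasite Nosema ceranae, with Black Queen Cell Virus (BQCV, a picorna-like RNA virus), with both, or with neither. Each of the 11 libraries was made from a pool of 4 brains. Cages held 30 workers with sugar water at 50%. There were 3 control, 3 Nosema, 3 BQCV and 2 co-infected libraries. The labels do not say whether the pools came from separate cages or colonies, so the p-values measure only the spread between these libraries.

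The deposited values are raw read counts per gene, given by NCBI Gene ID, for 11076 genes. CASAVA 1.8.2 and HTSeq, with no version, are named in the submitters' processing notes. The aligner, genome build, annotation release and strand setting of the counting are not given in the sources used here, so no positions are printed. Gene symbols came from a reference table that held 9042 of the IDs. The 2034 IDs that it lacked carried 4.95% of all counts and are named by ID. Most matched genes carry a locus symbol starting with LOC, and 467 have a descriptive symbol or synonym, of which 358 were tested. No function is given for the others.

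Library totals ran from 19630553 to 51437202 counts, and the 10 most abundant genes took 6.79% to 7.67% of them. A level of 3 counts corresponds to between 0.0583 and 0.153 CPM (read counts scaled by library size) in a library, and this floor covers counting error only. Control 2 and co-infected 1 had totals below the bound for a doubted library, which was set from the median total, and the counts of genes were also computed without them. No pair of libraries was a duplicate, since the lowest chi-square per degree of freedom between libraries was 10.8.

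Expression was tested in edgeR 4.0.16 under R 4.3.3 with TMM scaling, the default filter on low counts and a robust quasi-likelihood F-test. All 11 libraries shared 1 model with 7 residual degrees of freedom, because the co-infected group has 2 libraries. Of the genes in the table, 1070 had no count and 9266 were tested. The Benjamini-Hochberg threshold was 0.05. The biological coefficient of variation was 0.114. Levels are given as the mean and SD of CPM, and log2 fold changes with their standard error (SE). Each infection was compared with control, co-infection with each single infection, BQCV with Nosema, and the interaction tested whether the virus effect differed between bees with and without Nosema. Correlations of fold changes that share the control libraries were set against 100 simulations of unchanged groups with the same controls. Each simulation drew counts independently for each gene and library, with all 11 libraries.

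Genes named in the text were chosen by a rule. For infection against control they were the 12 higher and 12 lower genes with the smallest adjusted p among those past the threshold whose CPM ranges did not overlap. The averaged virus comparison, added later, took the same numbers and the other comparisons 5 of each, and where fewer than 5 genes passed, the 5 with the smallest p are named as not passing. The text names fewer in places, in rank order. From a list, up to 4 members with the smallest p are named where the list or a member passed. Outside this rule, Apid1, Fstl5, the Fabp gene with NCBI Gene ID 408689 and COX1 in BQCV against Nosema were chosen after their values were seen. Members of lists too small to test, and the most abundant members of the lists of other tissues, are named to give the values of those lists.

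In total 22 gene lists were fixed. They covered antimicrobial peptides, immune recognition and signalling, melanisation and serpins, haemocyte markers, RNA interference, royal jelly and gland products, fat body markers, retina markers, chemosensory proteins, neuropeptides, transmitter receptors, the circadian clock, activity-regulated genes, hormone and insulin signalling, glia markers, muscle and cuticle, heat shock proteins, detoxification, antioxidants, oxidative phosphorylation, ribosomal proteins, and glycolysis and sugar transport. They were tested with camera in limma 3.58.1 on log2 CPM with a prior count of 2 and a preset correlation of 0.01, and again with an estimated correlation and with fry. A list needed at least 3 tested members. The reference table holds no descriptions, so 5 lists could be tested as fixed. Members were therefore also assigned by gene symbol, an alternative chosen after seeing the data's gene names and before any test, which made 17 lists testable.

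Library numbers were checked for pairing with correlations of residuals from the group means. In the 3 groups of 3 libraries, the 9 pairs with the same number gave r from 0.16 to 0.34 and the 18 others from -0.27 to -0.027. The title and the description of the second co-infected library differ in number. By the description number the 6 pairs with co-infected libraries gave r from 0.16 to 0.4. By title number 2 the second library's 3 pairs gave r from -0.1 to -0.017. In a group of 2 the residuals mirror each other, so both ranges rest on the same difference between the co-infected libraries. In groups of 3, too, residuals cancel out, so positive same-number pairs push the r of the other pairs down. The description number was therefore used as a block in an alternative model with 5 residual degrees of freedom and a biological coefficient of variation of 0.0861, in which 83 genes passed for BQCV against control.

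The model, threshold, naming rule, lists as fixed and most alternatives were set before the data were examined. The alternatives were DESeq2 1.42.0, limma voom, RLE size factors, no filter on low counts, models of only the groups compared, blocks by title or description number, and leaving out each library. Thinning all libraries to the smallest total and leaving out both shallow libraries were chosen after seeing the data. So were the comparisons averaged over the other infection and the look-up of BQCV genes in co-infected against Nosema libraries. The methods were also tested on simulated data with 50 changed genes per fold. For BQCV against control, edgeR recovered 17, 38, 38 and 49 of them at folds of 1.25, 1.5, 2 and 4 and called 9 unchanged genes, while DESeq2 called 35 unchanged genes. For Nosema against control edgeR recovered 12, 32, 42 and 48, and for co-infection against control 9, 32, 40 and 46.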

Results

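The data were brain transcriptomes of 15-day-old worker bees in 4 groups, with 3 control, 3 Nosema, 3 BQCV and 2 co-infected libraries. Control libraries 1, 2 and 3 held 47245855, 19630553 and 47672800 counts in total. Nosema libraries held 40909787, 45156543 and 51437202 counts, BQCV libraries 24617943, 26868330 and 44125136, and co-infected libraries 20082425 and 29703934. Values are CPM, read counts scaled by library size, as mean ± SD, and log2 fold changes are given ± SE.

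The first question was what BQCV alone did to the brain. In BQCV brains 17 genes changed against control, 8 higher and 9 lower, and the named ones among them were chaperones and a yellow-family gene, all lower. Hsp90, a chaperone of kinases and hormone receptors, fell from 4470 ± 180 CPM in control to 3150 ± 180 CPM (n = 3 each), a log2 fold change of -0.51 ± 0.06 (adjusted p = 0.016). Hsc70-4, the constitutive cytosolic Hsp70 chaperone, fell from 8130 ± 230 to 6300 ± 160 CPM, a log2 fold change of -0.37 ± 0.059 (adjusted p = 0.041). Y-f, a member of the yellow family related to the royal jelly proteins, fell from 2560 ± 170 to 1890 ± 84 CPM (adjusted p = 0.036). The genes that rose have no descriptive symbol. Among them LOC100577849 rose 2.98-fold, the gene with NCBI Gene ID 727401 rose 2.72-fold from 7.18 ± 0.61 to 19.7 ± 4.1 CPM, and LOC552797 rose 2.13-fold from 46.8 ± 2.4 to 99.8 ± 16 CPM. LOC100577430, LOC409367 and LOC726375 rose 2.64-fold, 2.42-fold and 2.4-fold, and LOC726766 and LOC408434 rose 1.61-fold and 1.29-fold. LOC408864 fell to 0.648 of its control level, from 414 ± 38 to 268 ± 16 CPM, and LOC409300, LOC410516, LOC413386, LOC726793 and LOC409235 fell to between 0.765 and 0.823 of theirs. DESeq2 called 201 genes and limma voom 30, the model blocked by description number called 83, including all 17, and a model of only these groups called 0. The count was 9, 1 and 2 without control 1, 2 and 3, 10, 11 and 11 without Nosema 1, 2 and 3, and 0, 2 and 53 without BQCV 1, 2 and 3, and without both shallow libraries it was 0 (854 at an unadjusted p under 0.05, against 1056 with all libraries).

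**Figure D1:**
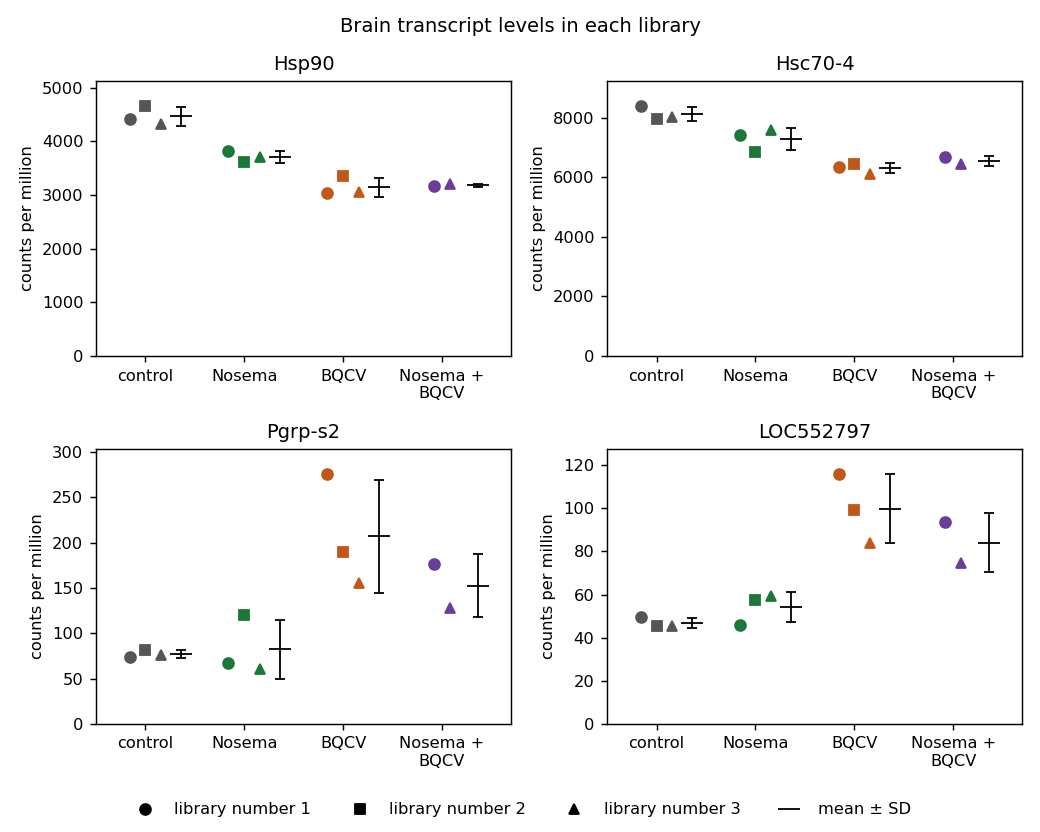
Expression of Hsp90, Hsc70-4, Pgrp-s2 and LOC552797 in CPM for each of the 11 libraries by group, with marker shape giving the library number and bars the mean ± SD. Hsp90 averaged 4470 CPM in control, 3720 in Nosema, 3150 in BQCV and 3180 in co-infected brains.

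Heat shock proteins were lower as a group in brains with BQCV alone. All 4 tested members had lower values, with a median log2 fold change of -0.26 (camera adjusted p = 4.9e-05, and adjusted p = 0.014 with an estimated correlation). Of these, 2 passed adjusted over the list alone and the same 2, Hsp90 and Hsc70-4, passed over all genes. In the blocked model the list passed at the preset correlation (adjusted p = 0.00051) and did not with an estimated correlation (adjusted p = 0.055). With members assigned by symbol, Cdc37, the cochaperone that brings kinases to Hsp90, had a log2 fold change of -0.17 ± 0.042 (adjusted p = 0.0034 over the list alone and 0.17 over all genes). That list of 5 passed (adjusted p = 1.2e-05, and adjusted p = 0.027 with an estimated correlation), but in the blocked model it had an adjusted p of 0.22 with an estimated correlation. The other 4 lists testable as fixed did not pass. Royal jelly and gland products had a median of -0.09 (adjusted p = 0.44), fat body markers -0.22 (0.64), retina markers -0.22 (0.2), and hormone and insulin signalling 0.02 (0.67). The retina list passed in the blocked model (adjusted p = 0.034, and adjusted p = 0.14 with an estimated correlation) and without control 3 (adjusted p = 0.02).

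Genes of glycolysis and sugar transport and antioxidant genes, assigned by symbol, were slightly lower in BQCV brains under the preset correlation. The 3 members for glycolysis and sugar transport had a median log2 fold change of -0.21 (adjusted p = 0.0096, but adjusted p = 0.35 with an estimated correlation). Tpi, triosephosphate isomerase, and Tret1, a trehalose transporter, each had -0.21 and passed adjusted over the list alone (adjusted p = 0.006), and neither passed over all genes. The 8 antioxidant members had a median of -0.11 (adjusted p = 0.031, but adjusted p = 0.35 with an estimated correlation), and Sod1, the copper and zinc superoxide dismutase, had -0.18 ± 0.049 (adjusted p = 0.03 over the list alone). Pgrp-s2, a peptidoglycan recognition protein, was 2.68-fold higher (log2 1.42 ± 0.29, adjusted p = 0.0063 over the list alone and 0.12 over all genes), while its list of 8 immune recognition genes had a median of 0.11 (adjusted p = 0.47). Antimicrobial peptides had a median of 0.08 and a mean of 0.96 (adjusted p = 0.47), the mean carried by the apidaecin gene Apid1 at 3.52 ± 1.2 (adjusted p = 0.33 over all genes), named after its values were seen. AGLU2, an alpha-glucosidase, had -0.6 ± 0.13 (adjusted p = 0.0098 over the list alone and 0.12 over all genes), in a gland list with a median of -0.25 (adjusted p = 0.23). The cytochrome P450 gene CYP6AS13 (LOC551028) had -0.32 ± 0.079 (adjusted p = 0.019 over the list alone and 0.17 over all genes).

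No other group assigned by symbol passed for BQCV. Medians were -0.17 for 25 muscle and cuticle genes (adjusted p = 0.16), -0.1 for 13 neuropeptides (0.37), -0.05 for 34 chemosensory genes (0.53), -0.04 for 30 transmitter receptors (0.53), 0.06 for 3 RNA interference genes (0.35) and -0.01 for 7 ribosomal proteins (0.88). Detoxification genes had a median of 0.02, a mean of -0.09 and a downward test (0.43). Oxidative phosphorylation genes had a median of 0.02, a mean of 0.06 and a downward test (0.87). Lists with fewer than 3 tested members were not tested. Among them, PPO, the prophenoloxidase gene that alone stood for melanisation and for haemocytes, had -0.22 and the activity-regulated transcript Kakusei 0.41. The clock genes Per and Cry2 had a median of 0.06 and the glia markers GlnS and Eaat-2 a median of -0.01.

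The comparison of Nosema with control asked what the gut parasite alone did to the brain. No single gene passed, and of the 5 lists testable as fixed only the heat shock group did. Its 4 members had a median log2 fold change of -0.11, with 3 lower (adjusted p = 0.027, but adjusted p = 0.13 with an estimated correlation), and 2 passed adjusted over the list alone against 0 over all genes. Averaged over virus status, a comparison chosen after seeing the data, this list did not pass for Nosema (median -0.01, adjusted p = 0.9). Hsp90 stood at 3720 ± 110 CPM against 4470 ± 180 in control (n = 3 each), a log2 fold change of -0.26 ± 0.06 that did not pass over all genes (adjusted p = 0.88). The other genes with the smallest p, none of which passed, were LOC412197 at 0.826 of its control level, LOC410820 at 1.26, LOC409881 at 0.369 and LOC409646 at 0.784. With members assigned by symbol, 26 of 30 transmitter receptors had higher values with a median of 0.09 (adjusted p = 0.0067, but adjusted p = 0.66 with an estimated correlation). Hormone and insulin genes had a median of 0.16 (adjusted p = 0.021, but adjusted p = 0.66 with an estimated correlation), and among these the ecdysone response genes Br-c, Ecr, Usp and E75 had 0.44, 0.39, 0.16 and 0.25, none past the threshold. Oxidative phosphorylation genes had a median of -0.11, with 13 of 18 lower (adjusted p = 0.015, but adjusted p = 0.66 with an estimated correlation). The heat shock list of 5 members by symbol passed as well (adjusted p = 0.0067, but adjusted p = 0.18 with an estimated correlation). The edgeR count of 0 genes stood beside 387 at an unadjusted p under 0.05, where 463 would be expected with no change. DESeq2 called 2 genes and limma voom 0. The unadjusted number was 566 blocked by description number, 1519 without control 1 and 207 without control 2, so it lay on both sides of 463. The heat shock call as fixed was lost in the blocked model (adjusted p = 0.076), without control 1 (0.1), control 2 (0.065), Nosema 1 (0.09) or both shallow libraries (0.11), and without Nosema 2 the hormone and insulin list passed too (0.033).

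Co-infected brains were compared with control to find the response to both pathogens. No gene passed, and Hsp90 had the smallest p, at 3180 ± 26 CPM (n = 2) against 4470 ± 180 (n = 3), a log2 fold change of -0.49 ± 0.068 (adjusted p = 0.18). The gene with NCBI Gene ID 727401 was at 17 ± 4.3 CPM against 7.18 ± 0.61, 2.35-fold its control level. LOC725378, LOC551308 and LOC551422 were at 1.23, 1.2 and 1.43 of theirs, and these also did not pass. Heat shock proteins as fixed had a median of -0.14, with 2 of 4 lower and 2 higher (camera adjusted p = 0.11, fry adjusted p = 0.0032), and 2 passing adjusted over the list alone and 0 over all genes. With members assigned by symbol, 4 groups were lower under the preset correlation. Muscle and cuticle genes had a median of -0.26, with 20 of 25 lower (adjusted p = 0.015, but adjusted p = 0.38 with an estimated correlation). Cpap3-b, a cuticular protein, had -0.44 ± 0.11, and 0 members passed adjusted over the list alone. Chemosensory genes had a median of -0.26, with 24 of 34 lower (adjusted p = 0.037, but adjusted p = 0.33 with an estimated correlation). The odorant binding protein gene Obp18 had -2.66 ± 0.82, and here too 0 members passed adjusted over the list alone. Oxidative phosphorylation genes had a median of -0.15, with 14 of 18 lower (adjusted p = 0.015, but adjusted p = 0.38 with an estimated correlation), and Cox6b1 at -0.26 and ATP5G2 at -0.21 passed adjusted over the list alone. Heat shock genes by symbol had a median of -0.17, with 3 of 5 lower (adjusted p = 0.015, but adjusted p = 0.33 with an estimated correlation). The antioxidant list of 8 did not pass (median -0.15, 5 lower and 3 higher, camera adjusted p = 0.078). Of its members 4 passed adjusted over the list alone and 0 over all genes. The edgeR count of 0 genes stood beside 1050 at an unadjusted p under 0.05, with 178 genes by DESeq2 and 0 by limma voom.

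**Figure D2:**
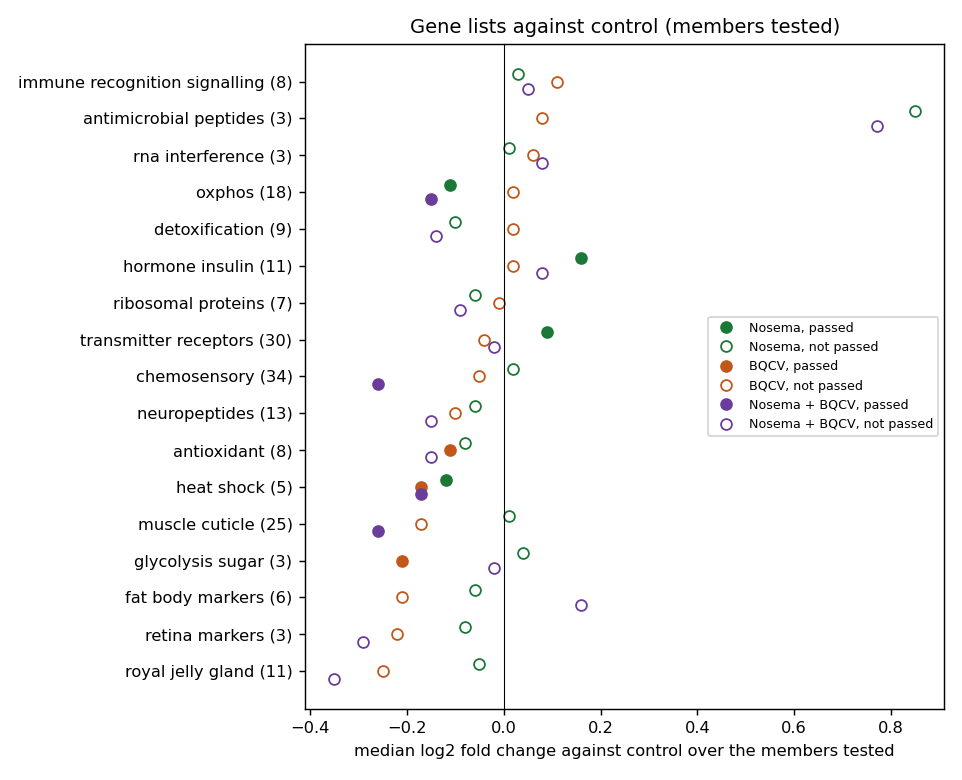
Median log2 fold change against control of each gene list, with members assigned by symbol and their number in brackets, for Nosema, BQCV and co-infection. Filled points passed camera at the preset correlation, and with an estimated correlation only heat shock in BQCV brains also passed (adjusted p = 0.027, but adjusted p = 0.22 in the blocked model).

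Co-infection was set against each single infection to see what the second pathogen added. Against Nosema alone no gene passed, and the smallest p values belonged to genes also named for BQCV. The gene with NCBI Gene ID 727401 was at 17 ± 4.3 CPM (n = 2) against 6.37 ± 0.97 (n = 3), LOC100577430 was 2.55-fold higher and LOC726793 was at 0.814 of its level (adjusted p = 0.25 for each). LOC727419 and the gene with NCBI Gene ID 100577950 were 1.52-fold and 1.88-fold higher and did not pass. The edgeR count of 0 stood beside 903 genes at an unadjusted p under 0.05, with 75 genes by DESeq2, 0 by limma voom and 1 in a model of only these groups, and it was 3 without BQCV 3. Against BQCV alone no gene passed, and LOC411935 had the smallest p at 62.6 ± 7.8 CPM (n = 2) against 32.5 ± 4.7 (n = 3), 1.92-fold higher (adjusted p = 0.35). LOC551422, LOC100578706, LOC409370 and LOC410874 were 1.38-fold, 1.2-fold, 1.23-fold and 1.2-fold higher, and none passed. The edgeR count of 0 stood beside 635 genes at an unadjusted p under 0.05, with 36 genes by DESeq2 and 0 by limma voom. The interaction, the test of whether the virus effect differed with Nosema, also called 0 genes by edgeR, DESeq2 and limma voom. It had 260 genes at an unadjusted p under 0.05, where 463 would be expected with no change. Without control 1 the interaction had 706 such genes, and without Nosema 2 it had 149. Its smallest p values belonged to LOC410398 (log2 -1.02), LOC726611 (-0.62), LOC726529 (-0.33), LOC410516 (0.28) and the gene with NCBI Gene ID 100579044 (-3.59), all with an adjusted p of 1.

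BQCV brains differed from Nosema brains in 64 genes, 38 higher and 26 lower in BQCV, a comparison that shares no control library. The largest of the named increases were LOC100577430 at 3.25-fold, from 15.5 ± 2.4 to 50.5 ± 13 CPM, and the gene with NCBI Gene ID 727401 at 3.08-fold, from 6.37 ± 0.97 to 19.7 ± 4.1 CPM (n = 3 each, adjusted p = 0.012 for both). LOC409367, LOC726766 and LOC408434 rose 2.71-fold, 1.74-fold and 1.32-fold. LOC410820 fell to 0.677 of its Nosema level, from 417 ± 26 to 282 ± 17 CPM, and LOC408864, LOC409300, LOC726793 and LOC413386 fell to 0.683, 0.786, 0.804 and 0.749. COX1, the mitochondrially encoded subunit of cytochrome c oxidase, was the 1 called gene with a descriptive symbol, chosen after its values were seen, and was 1.49-fold higher (log2 0.58 ± 0.085, adjusted p = 0.024). DESeq2 called 480 genes, limma voom 93, the model blocked by description number 236, including all 64, a model of only these groups 41, and the count was 30 without both shallow libraries. The count was 168, 37 and 36 without control 1, 2 and 3, 0, 0 and 1 without Nosema 1, 2 and 3, and 0, 0 and 186 without BQCV 1, 2 and 3.

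Across the 3 infections, 0 genes passed against control in all of them with edgeR, against 0.02 on average in simulated unchanged groups. DESeq2 gave 1 and limma voom 0. The edgeR value says nothing about a shared response, because Nosema and co-infection each called 0 genes. Across 9266 genes, which are not independent replicates, the fold changes of BQCV and co-infection correlated with r = 0.53 (rho = 0.54), above the 95th percentile of 0.48 that shared controls gave in simulation. The covariance was 0.0427 against 0.0284 in simulation. Nosema and co-infection gave r = 0.47 (rho = 0.38) against a 95th percentile of 0.48. Nosema and BQCV gave r = 0.36 (rho = 0.21) against 0.56, so neither pair passed. The simulation drew every gene and library independently, without the correlation between libraries of the same number. The Nosema and BQCV value also lay below its simulated mean of 0.5. These bounds may therefore be misplaced. Passing one does not by itself show a shared response, and staying below one does not argue against it. The BQCV and co-infection value was 0.44 without BQCV 1, 0.43 without BQCV 3, 0.35 without co-infected 1 and 0.37 without co-infected 2. Nosema and co-infection gave 0.65 without control 1 and 0.6 without control 3, and Nosema and BQCV 0.58 without control 1. The bounds were simulated for all 11 libraries only. Leaving out a library changes what shared controls give, so these values cannot be called past or below a bound. The 3 control libraries are too few to split between comparisons, so part of each r may come from shared controls.

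The BQCV genes were looked up in co-infected against Nosema brains, a comparison chosen after seeing the data. It shares no library with BQCV against control. The spread used to select the genes came from all 11 libraries, however, and also gave the p-values of the look-up. In co-infected against Nosema brains, all 17 had the same sign as in BQCV against control, and 12 passed adjusted over the list alone. The gene with NCBI Gene ID 727401 had log2 1.44 with BQCV alone and 1.41 beside Nosema, and LOC100577430 had 1.4 and 1.35. Hsp90 had -0.51 and -0.23 (adjusted p = 0.012 over these genes alone), and Hsc70-4 had -0.37 and -0.15 (adjusted p = 0.055). The median ratio of the log2 fold changes was 0.58, which selecting the genes on BQCV against control can lower. The libraries of both comparisons are also not fully independent of each other. Those with the same number deviate together across groups (r from 0.16 to 0.41). In the model blocked by description number, 81 of 83 genes had the same sign. Across all genes r was 0.27 and rho 0.39, and the matching value for Nosema, with and without the virus, was r = 0.16 and rho = 0.25.

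**Figure D3:**
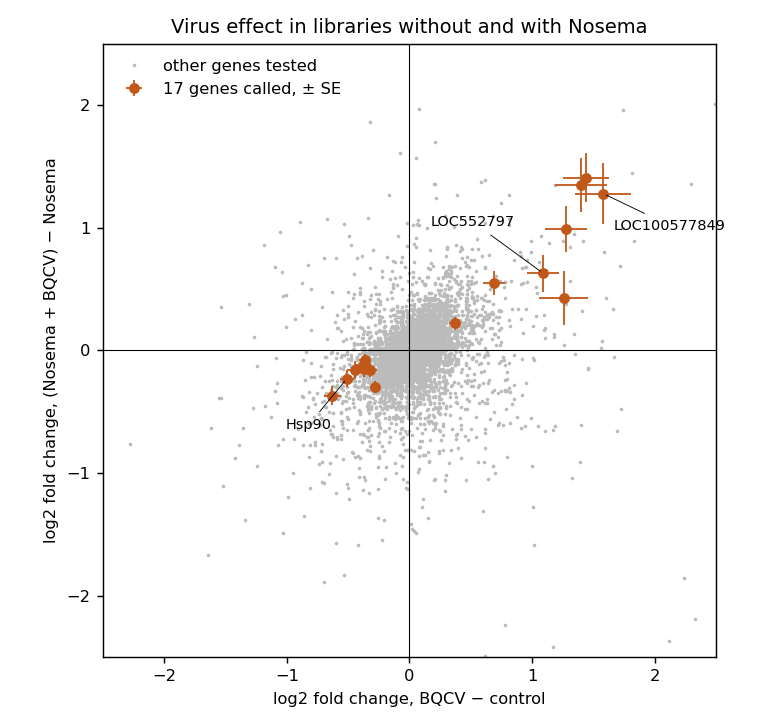
Log2 fold change of BQCV against control (horizontal) and of co-infected against Nosema brains (vertical), which share no library, with the 17 called genes marked with their SE. All 17 lie on the same side of 0 on both axes, and 17 of the 9266 tested genes fall outside the plotted range.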

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

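Thinning, leaving out both shallow libraries, members assigned by symbol and the averaged comparisons were chosen after seeing the data. No called gene changed sign in any setting. The interaction stayed at 0 in every setting run. The cause of the differences below was not tested, except that fewer libraries or groups leave fewer degrees of freedom.

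DESeq2 called 2 genes for Nosema, 201 for BQCV and 178 for co-infection against control, 75 for co-infection against Nosema, 36 against BQCV, 480 for BQCV against Nosema, 563 for the averaged virus, 77 for averaged Nosema, and 1 in all 3 infections. In simulated data it called more unchanged genes than edgeR in each comparison. With only the groups compared, BQCV against control gave 0, co-infection against Nosema 1 and BQCV against Nosema 41. Blocked by title number these were 41 for BQCV against control, 121 for BQCV against Nosema and 1 for averaged Nosema. Blocked by description number they were 83, 236 and, for the averaged virus, 380. Limma voom gave 30 and thinning 26 for BQCV against control. Without both shallow libraries BQCV against control gave 0, BQCV against Nosema 30 and the averaged virus 0. RLE size factors gave 15, 66 and 124 genes for these comparisons and no filter 17, 59 and 100, close to 17, 64 and 114.

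Leaving out each library gave 0 to 53 genes for BQCV against control, 0 to 186 for BQCV against Nosema, 1 to 217 for the averaged virus, 0 to 3 for averaged Nosema, 0 to 3 for co-infection against Nosema, and 0 to 0 for Nosema against control, co-infection against control and against BQCV, the interaction and all 3 infections. Where this left 1 co-infected library, it was assumed to vary like the other groups.

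The correlation of Nosema and co-infection was 0.49 with the title block. That of BQCV and co-infection was 0.45 with no filter, 0.47 with the title block and 0.34 without both shallow libraries. The bounds were simulated for the main model only, so these values cannot be called past or below them. Leaving out each library gave 0.22 to 0.58 for Nosema and BQCV, 0.2 to 0.65 for Nosema and co-infection, and 0.35 to 0.69 for BQCV and co-infection.

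For Nosema against control, the 1 list passing became 0 with either block, without both shallow libraries, and with an estimated correlation, and 4 with members by symbol (4 with the block, 0 with an estimated correlation). For BQCV against control it became 2 with either block and 3 with members by symbol (3 with the block). For co-infection against control, 0 became 1 with the title block, 1 with fry and 4 with members by symbol (4 with the block). Leaving out each library gave 0 to 2 lists for Nosema, 1 to 2 for BQCV and 0 to 0 for co-infection. In simulated data with these library totals, 17 of 50 genes were recovered for BQCV at a fold of 1.25, and no simulation varied the depth.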

Other observations

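The averaged comparisons and the look-up of BQCV genes were chosen after seeing the data. So were the tests for other tissue and for a response to the virus. The criterion of the last was changed once after a first result was seen.

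Averaging the virus effect over bees with and without Nosema set 5 libraries with the virus against 6 without it and called 114 genes, 64 higher and 50 lower. Pgrp-s2, a peptidoglycan recognition protein, rose 2.23-fold (log2 1.16 ± 0.21, adjusted p = 0.044). Both genes with the symbol Fabp, which encode fatty acid binding proteins, fell, to 0.822 and 0.868 of their level (adjusted p = 0.03 and 0.038). Cpap3-b, a cuticular protein, fell to 0.769 and Fstl5, a follistatin-like gene, to 0.877 of their levels (Fstl5 and the Fabp gene at 0.868 were chosen after their values were seen), while COX1 rose 1.24-fold (adjusted p = 0.049). Hsp90 fell to 0.776, from 4090 ± 430 to 3160 ± 130 CPM, and Hsc70-4 to 0.835. Heat shock proteins as fixed had a median log2 fold change of -0.14, with 4 of 4 lower (adjusted p = 0.013, but adjusted p = 0.092 with an estimated correlation, and adjusted p = 0.23 with it in the blocked model), and 2 passed adjusted over the list alone. With members assigned by symbol the list had an adjusted p of 0.0051, but an adjusted p of 0.16 with an estimated correlation. Muscle and cuticle genes, assigned by symbol, had a median log2 fold change of -0.25, with 21 of 25 lower (adjusted p = 0.0051, but adjusted p = 0.39 with an estimated correlation), and 2 passed adjusted over the list alone, of which Cpap3-b passed over all genes. Among genes with no descriptive symbol, the gene with NCBI Gene ID 727401 rose 2.69-fold, from 6.77 ± 0.85 to 18.6 ± 3.9 CPM, LOC409367 rose 2.2-fold, and LOC408864 fell to 0.708 of its level. Apid1, an apidaecin also chosen after its values were seen, ran from 18.2 to 71.8 CPM with the virus and from 1.27 to 23.5 CPM without it, and did not pass (log2 2.43 ± 0.84, adjusted p = 0.2). The model blocked by description number called 380 genes, including all 114. DESeq2 called 563 and limma voom 92. The count was 42, 14 and 14 without control 1, 2 and 3, 14, 21 and 10 without Nosema 1, 2 and 3, 15, 14 and 217 without BQCV 1, 2 and 3, 1 and 32 without co-infected 1 and 2, and 0 without both shallow libraries.

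Averaged over virus status, Nosema changed 0 genes by edgeR, beside 845 at an unadjusted p under 0.05, 77 by DESeq2 and 0 by limma voom, with 3 without control 1 and 1 without Nosema 1. LOC410820 was 1.29-fold and LOC411935 1.55-fold higher (adjusted p = 0.18), and LOC411252, LOC408369 and LOC410874 were 1.46-fold, 1.45-fold and 1.14-fold higher (adjusted p = 0.21), and none passed. Oxidative phosphorylation genes, assigned by symbol, had a median log2 fold change of -0.13 with 17 of 18 lower (adjusted p = 0.00056, but adjusted p = 0.88 with an estimated correlation). Heat shock proteins as fixed did not pass here, with a median of -0.01, a mean of 0.02, a downward test and 2 of 4 higher (adjusted p = 0.9).

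The genes changed with the virus, averaged over Nosema status, were counted again in splits of the 11 libraries. Of 100 splits, 1, the real one, gave as many genes (114, highest other 26). Labels were also swapped only within the 5 pairs of virus and no-virus libraries with the same number. There 1 of 32 labellings, again the real one, gave as many genes (highest other 0). In the blocked model the real labelling gave 380 genes against a highest other of 32. No other labelling tried gave as many genes, but the comparison was chosen after seeing the data. The splits also treat the pools as separate units, which the labels do not state, so chance is not excluded. Depth as the whole cause is argued against, because 84 of the 114 genes passed with the same sign in libraries thinned to 1 depth. Other tissue in the dissected pools cannot be told apart, since the smallest adjusted p of the 4 tissue lists was 0.39 with an estimated correlation while medians were -0.43 for gland, -0.01 for fat body, -0.23 for retina and -0.25 for muscle and cuticle, whose most abundant members averaged 616 CPM (Hbg3), 3930 CPM (Tsf1), 121 CPM (Lop1) and 33.7 CPM (CPF2). A response to the virus stays open beside other tissue and differences that go with depth. In co-infected against Nosema libraries 17 of 17 genes kept their sign, and 12 passed adjusted over these genes alone. Those libraries entered the selection through the shared spread, though not through the means compared. Other splits of those libraries gave up to 16 of 17, which decides nothing, because they hold part of the virus contrast themselves.

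Libraries with the same number deviate together, with r from 0.16 to 0.41 in 15 pairs against at most 0.1 in 30 others. Residuals cancel out within a group and those of the co-infected libraries mirror each other, so these pairs are not independent. Unequal counting depth is argued against, because the lowest r was still 0.12 in thinned libraries. Thinning cannot remove other differences that may go with depth. Whether a few genes carry it stays open: without the 161 genes that differed between numbers the lowest r was 0.09, just under the bound of 0.1, while the highest was 0.34. Those genes were chosen for the pattern, so this does not decide it. The labels do not say what the numbers stand for, and no biological explanation was tested.

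At an unadjusted p under 0.05, 1056 genes differed from control with the virus alone and 1050 with both pathogens. DESeq2 called 201 and 178. At the adjusted threshold in edgeR, 17 genes passed with the virus alone, and with both pathogens 0. Fewer co-infected libraries could be the reason, since with 2 of the 3 BQCV libraries the count was 0, 2 or 53, depending on which was left out. The SE was 1.12 times as large with co-infection (median over the 17 genes). In simulated data edgeR recovered 9, 32, 40 and 46 of 50 genes for co-infection at folds of 1.25, 1.5, 2 and 4. It recovered 17, 38, 38 and 49 for BQCV, but 12, 32, 42 and 48 for Nosema, which also had 3 libraries. Each comparison was simulated with other genes, so these values do not show an effect of library number. A weaker response beside Nosema could be another reason. The median ratio of log2 fold changes over the 17 genes, co-infection over BQCV, was 0.7 with both against control. With co-infection against Nosema instead, which sets aside an effect of Nosema itself, it was 0.58. However, these genes were selected with the virus alone, which can lower both ratios, and 0 of them passed the interaction adjusted over them alone. The explanations cannot be told apart, because the largest count with 2 libraries, 53, and the smallest lie on both sides of 17.

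For BQCV against control 1 of 10 splits, the real one, gave as many genes (17, highest other 0), and for BQCV against Nosema 1 of 10 (64, highest other 0). These splits are too few for a share under 0.05. For Nosema against control the real count was 0, which every split equals or exceeds by construction (10 of 10), so this says nothing about chance. The highest other gave 395 genes by setting control 1, Nosema 1 and Nosema 2 against the rest. That split points to a structure of the samples. It parts 1 pair of equal number and gave 583 genes in the model blocked by description number, so the block did not remove it. No infection comparison called as many genes with that block. The splits that part all 3 pairs of equal number gave 0. For averaged Nosema the real count was also 0, so the 100 of 100 splits with as many genes are likewise uninformative, and the highest other gave 59.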
